A study of Homo sapiens with 54 samples.

How the data were processed

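Gene expression was measured in HEK cells on 54 Affymetrix whole-transcript gene arrays, 1 per sample, after transfection with a negative control siRNA or 1 of 3 siRNAs against WFS1. Samples were grouped by the siRNA and the time after transfection given in the labels, which makes 16 groups of 1 to 5 arrays. The labels also give a replicate number, and their descriptions a running number from 1 to 40 at 24 and 48 h and from 41 to 79 at 72 and 96 h, whose meaning is not given in the sources used here.

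The deposited table holds 1 log2 value per probe set and array, with 2 decimals. The submitters' processing notes name MAS5 and RMA, without versions and without saying what each was used for. The background correction, the normalization and the log base are not given in the sources used here, and the log2 scale is read from the range of the values (1.18 to 14.58) and from array medians of 6.77 to 6.93, which lie close together as in values normalized between arrays. The values were used as deposited. The series names no genome build, and no coordinates are given.

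The table holds 32321 probe sets. The platform annotation gave 1 gene symbol for 19158 of them and several for 1388, and did not list 11775, which are unnamed here. Of the probe sets with 1 symbol, 19128 matched a RefSeq gene by its gene identifier and 30 did not, and no symbol had to be updated. Where a gene had more than 1 probe set (637 genes), the probe set with the highest mean over all arrays was used. This left 18404 genes.

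Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without an intensity trend) on the log2 values, in 1 model of 16 group means over all 54 arrays with 38 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes within a comparison, with a threshold of 0.05. The comparisons were the equal-weight mean of the 3 siRNA groups against control at each time, each siRNA against control, genes past the threshold with the same sign for all 3 siRNAs, an F-test of differences among the siRNAs, an F-test of differences of the mean siRNA effect among times, the same effect at 72 h against 48 h, and control cells at 48 h against 24 h and at 96 h against 72 h. Times on either side of the running number 40 were not compared within control cells, since they could belong to different batches. Gene lists and marker lists written before the data were examined were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, adjusted over lists and times. WFS1 was also tested alone with an exact permutation test within each time, chosen after seeing the data.

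The genes named were chosen by a rule fixed before the data were examined. For each comparison of the mean siRNA effect it takes WFS1 and the 10 highest and 10 lowest genes by log2 fold change among those past 0.05 with the same sign for all 3 siRNAs, and from each list up to 2 members per direction past 0.05. It takes the 2 highest and 2 lowest for a single siRNA, the 5 smallest p for the tests of differences, and the 5 highest and 5 lowest for control cells. Where none passed it takes the 3 genes with the smallest p, and for a list called by camera without a passing member up to 2 members with the smallest p. Only part of these are printed. In the closing sections, genes that passed only without the 7 low-correlation arrays or with the array SD as a covariate lie outside this rule and were chosen after their values were seen.

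Arrays were compared by the median of their Pearson correlations with the other arrays over the 18404 genes. A fence 3 interquartile ranges below the first quartile (0.985) left 7 arrays outside. The rule for this fence was chosen after seeing the data, and no array was removed from the reported comparisons.

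The alternatives were a fit on the arrays of the compared time only, the replicate number within a time as a block, a filter that kept the 12808 genes with a mean above the 40th percentile of probe sets, a further quantile normalization, the running number as a covariate, an intensity trend with robust variance, the mean of a gene's probe sets, the mean over 2 of the 3 siRNAs, an estimated correlation for the lists, and leaving out each array in turn. Leaving out the 7 low-correlation arrays, the same with the replicate block, the array's standard deviation (SD) as a covariate, and a mean of the siRNA effect over the 4 times were added after seeing the data. Array weights estimated by limma were tried, did not converge and were not used.

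The steps were tested on simulated data for the 18404 genes with the groups and gene-wise spread of the study, in which 200 genes were changed. The simulated noise was independent between genes and arrays, and no array stood apart. In the data 1 component held 52.7% of the variance left within groups, so recovery there can differ from the shares below. For the mean siRNA effect, a log2 change of 1 was recovered in 90.5%, 99.5%, 100% and 98% of the genes at 24, 48, 72 and 96 h, and a change of 0.5 in 14.5%, 66.5%, 77% and 42.5%. A change of 0.25 was recovered in 0%, 1%, 6% and 1%. For differences among siRNAs a log2 change of 1 in 1 siRNA was recovered in 78.5%, 97.5%, 98.5% and 95.5%.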

Results

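WFS1 encodes wolframin, a membrane protein of the endoplasmic reticulum (ER) whose loss causes Wolfram syndrome. HEK cells, a human embryonic kidney cell line, were transfected with a negative control siRNA or with 1 of 3 siRNAs against WFS1, and harvested after 24, 48, 72 or 96 h. Expression was measured on 54 Affymetrix whole-transcript gene arrays, 1 per RNA sample, which fall into 16 groups of siRNA and time. The control groups held 2, 4, 5 and 3 arrays at 24, 48, 72 and 96 h. siRNA1 had 2, 4, 5 and 3 arrays, siRNA2 had 2, 4, 4 and 3, and siRNA3 had 1, 4, 5 and 3. The number of arrays limits the precision of each value. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

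The median log2 value per array lay between 6.77 and 6.93, and no pair of arrays held identical values. The median correlation of an array with the other arrays was 0.993 in the middle of the 54 arrays. It was below 0.985, a fence set 3 interquartile ranges under the first quartile, in 7 arrays. These were control arrays at 24 h (replicate 2, 0.981), 72 h (replicate 3, 0.926) and 96 h (replicates 1 and 3, 0.982 and 0.974), siRNA2 at 96 h (replicate 1, 0.975) and siRNA3 at 48 h (replicates 1 and 3, 0.967 and 0.975). Among the other arrays the lowest median correlation was 0.987. The same 7 arrays had the lowest standard deviations (SD) of the log2 values over probe sets. All 54 arrays entered the comparisons. Values without these 7 arrays, chosen after seeing the data, are given where they change a call.

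**Figure D1:**
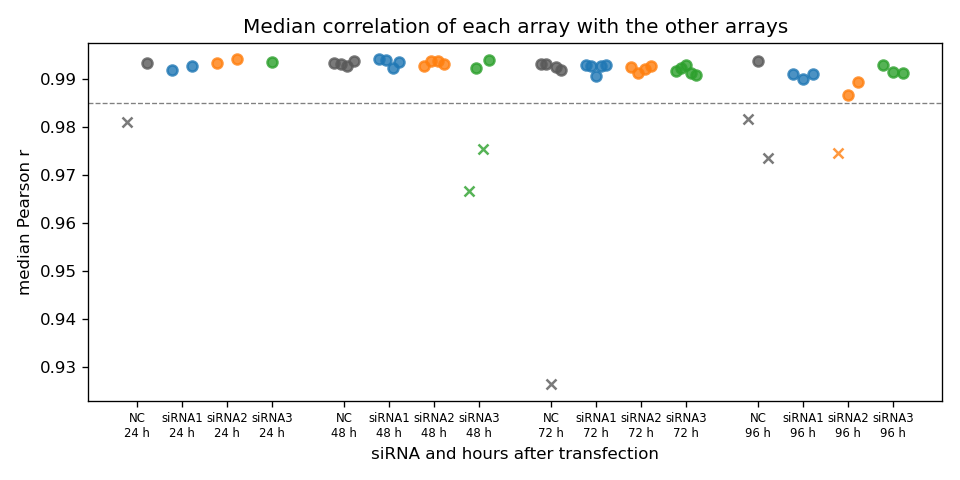
The median Pearson correlation of each of the 54 arrays with the other arrays is plotted on the y axis by siRNA and hours after transfection on the x axis (NC, negative control; 1 point per array). Crosses mark the 7 arrays below the dashed line at 0.985, the lowest of which is a 72 h control array at 0.926.

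WFS1, measured by probe set 8093906, was lower with every siRNA at every time, with 12 of 12 differences from control below 0 and 39 of 40 siRNA arrays below the control mean of their time. At 72 h its log2 level was 7.03 ± 0.11 in control cells (SD, n = 5) and 6.64 ± 0.15 over the siRNA arrays (SD, n = 14), a change of -23.8%, and 14 of 14 siRNA arrays lay below the lowest control array. The 72 h difference from control was -0.30 for siRNA1, -0.42 for siRNA2 and -0.46 for siRNA3. At 24 h WFS1 was at 7.15 ± 0.06 in control (SD, n = 2) and 6.78 ± 0.08 with siRNA (SD, n = 5), at 48 h at 6.93 ± 0.19 (n = 4) and 6.69 ± 0.12 (n = 12), and at 96 h at 6.81 ± 0.14 (n = 3) and 6.58 ± 0.17 (n = 9). Two-sided exact permutation tests of WFS1 alone, all siRNA arrays of a time against its control arrays, gave p = 8.6e-05 at 72 h (Benjamini-Hochberg adjusted 3.44e-04 over 4 tests), the smallest value this design can give. The exact p was 0.00934 at 48 h (adjusted 0.0187), 0.0476 at 24 h (adjusted 0.0635, the smallest raw p that design allows) and 0.0818 at 96 h. For single siRNAs the exact permutation p at 72 h was 0.00794 for each of the 3 (adjusted 0.0317 over 12 tests). At 24 and 96 h no single siRNA could pass, since 1 split is 0.167 or 0.333 of all splits at 24 h and 0.05 at 96 h. At 48 h the lowest adjusted exact p was 0.0857 for siRNA2 (unadjusted 0.0286). There 4 of 4 siRNA2 arrays lay below the lowest control array, so no smaller p was possible. The single-siRNA tests therefore do not separate 72 h from the other times. Without the 7 low-correlation arrays, 1 of them a 72 h control, the differences at 72 h were -0.30, -0.42 and -0.46. The exact permutation p of siRNA1, siRNA2 and siRNA3 was then 0.00794, 0.0286 and 0.0159. Adjusted over 12 tests it was 0.0857 each, since the adjustment ties the smaller values to the larger ones. In the limma model over 18404 genes, the mean siRNA effect on WFS1 was -0.36 at 24 h (SE 0.12, adjusted p = 0.873), -0.24 at 48 h (SE 0.08, adjusted p = 0.931), -0.39 at 72 h (SE 0.08, adjusted p = 0.0466) and -0.22 at 96 h (SE 0.10, adjusted p = 0.460). The 72 h limma call was held in 2 of the 19 fits that left out 1 array of that time, with values from -0.43 to -0.37. At 96 h the values in such fits ran from -0.28 to -0.14, the latter without control replicate 3.

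**Figure D2:**
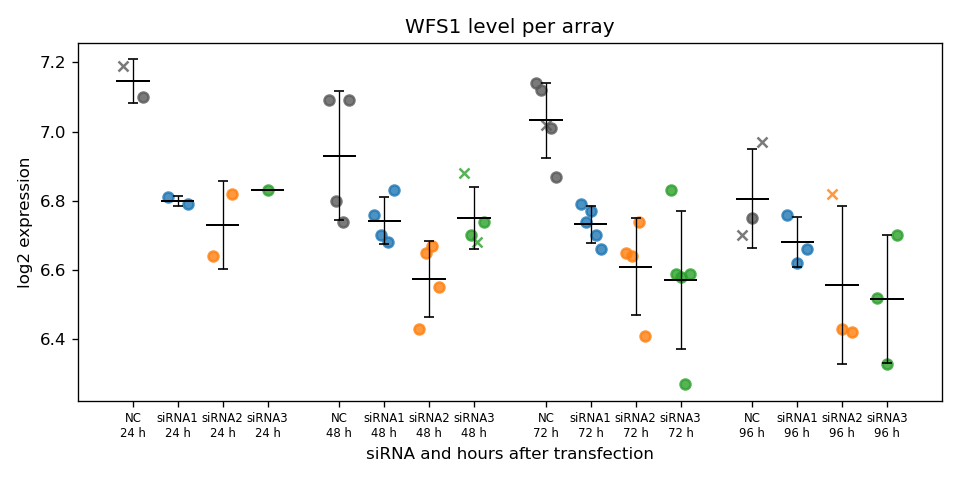
The log2 level of WFS1 on each array (y axis) is plotted by siRNA and hours after transfection (x axis), with black lines for group means, bars for SD and crosses for the 7 low-correlation arrays. At 72 h the siRNA arrays lie between 6.27 and 6.83, below the control arrays at 6.87 to 7.14.

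The mean of the 3 WFS1 siRNAs was compared with control at each time, which asks for the shared response to silencing. At 24 h no gene passed at an adjusted p of 0.05 in limma, and 495 genes had an unadjusted p under 0.05. Without any change a share of 0.05 of the 18404 genes is expected to have such a p, which is more than this count. Counts at an unadjusted p, here and below, are to be read against that share. The genes with the smallest p were RP1, a photoreceptor microtubule protein gene (-0.56, SE 0.14), RNU5D-1, a U5 small nuclear RNA gene (-1.46, SE 0.38), and CXCL11, a chemokine gene (-0.55, SE 0.15), each with an adjusted p of 0.873. The control levels of RP1 (3.48) and CXCL11 (4.41) lie below the limit of the filter on dim probes (6.29). RNU5D-1 was lower mainly with siRNA1 (8.99 against 11.44 and 11.88 with siRNA2 and siRNA3), and its mean effect was -0.91 without siRNA1 replicate 3 and -2.02 without replicate 4. Among the fixed gene lists, mitosis genes lay higher, with a median log2 difference of 0.21 and 28 of 31 members positive, including CENPE (0.56) and HMMR (0.51). Proteasome genes also lay higher (0.18, 25 of 28 positive, PSMA6 at 0.56), as did mitochondrial ribosome (0.08), DNA replication (0.10), cytosolic ribosomal protein (0.06), mitochondrial dynamics (0.06) and heat shock genes (0.08). Replication-dependent histones lay lower (-0.17, 2 of 26 positive, H4C1 at -0.41 and H4C3 at -0.47, and a median of -0.11 without siRNA1 replicate 3), together with NF-kB and cytokine genes (-0.19, 2 of 20 positive, CXCL3 at -0.33) and immediate early genes (-0.14, NR4A1 at -0.31). These 10 lists passed limma's camera test at a preset correlation of 0.01, and no member passed, either over all genes or adjusted over the list alone. With an estimated correlation no list passed (adjusted p = 0.776 to 0.778). Control replicate 2 of this time is 1 of the 7 low-correlation arrays. Without it 1 control array remained at this time. Mitosis genes then had a median of 0.05 and were no longer called, and the proteasome median turned to -0.04. The median of respiratory complex I, 0.08 over all arrays and not called, turned to -0.15 without control replicate 2. Without control replicate 4 instead it was 0.37, so its direction rested on which single control array was used.

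At 48 h no gene passed in limma, and 153 had an unadjusted p under 0.05. PTDSS1, the gene of phosphatidylserine synthase 1, was at -0.28 (SE 0.09), ASPA, the gene of aspartoacylase, at 0.31 (SE 0.09) and PAGE2, a cancer-testis antigen gene, at 0.51 (SE 0.17), each with an adjusted p of 0.931. PTDSS1 was lower mainly with siRNA2 (10.15, against 10.55 and 10.36 with siRNA1 and siRNA3 and 10.64 in control). Without the 7 low-correlation arrays its difference with siRNA3 was -0.05. The control levels of ASPA (2.7) and PAGE2 (3.2) lie below the limit of the filter on dim probes (6.29). Fixed lists lay slightly lower, among them ER chaperones (-0.10, 3 of 29 positive, CALR at -0.13), autophagy and lysosome genes (-0.09, 5 of 32), neurodegenerative disease genes (-0.07, 2 of 30, APP at -0.12), heat shock genes (-0.09, 1 of 17, HSPA8 at -0.10) and hypoxia and glycolysis genes (-0.08, 3 of 31, ENO1 at -0.10). Targets of the integrated stress response had a median of -0.06 (6 of 32 positive), ER stress sensors and WFS1-related genes -0.08 (4 of 18), extracellular matrix genes -0.08 (7 of 27), cholesterol synthesis genes -0.09 (3 of 19) and complex I genes -0.06 (4 of 34). NF-kB and cytokine genes lay higher (0.04, 14 of 20 positive, IL1B at 0.24 and IL6 at 0.21). Camera called 16 lists at 48 h, with no member past 0.05 over all genes or adjusted over the list alone, and none with an estimated correlation (adjusted p = 0.776 to 0.778). Of 16 fits that left out 1 array, complex I was called in 8, stress response targets in 10 and autophagy genes in 15, and none of these 3 was called without control replicate 3 (-0.05, -0.03 and -0.06). ER chaperones were called in all 16, with a median of -0.06 without that array. No list was called without the 7 low-correlation arrays, 2 of which were siRNA3 arrays of this time.

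At 72 h WFS1 fell by 0.39 (log2) and ISOC1, a gene of an isochorismatase domain protein, rose by 0.36 (SE 0.07, adjusted p = 0.0456), from 9.04 ± 0.23 in control (SD, n = 5) to 9.35 ± 0.07, 9.43 ± 0.05 and 9.42 ± 0.05 with siRNA1, siRNA2 and siRNA3 (SD, n = 5, 4 and 5). These were the 2 genes that passed in limma, while 3946 had an unadjusted p under 0.05, 2279 of them higher and 1667 lower (780, 442 and 338 without the 7 low-correlation arrays). PDIA4, an ER disulfide isomerase gene, was at 0.37 (SE 0.08, adjusted p = 0.122). ISOC1 passed in 5 of the 19 fits that left out 1 array, and without control replicate 3 its difference was 0.26. With the 7 low-correlation arrays left out, 6 genes passed.

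Over all arrays, genes of mitochondria, protein turnover and cell division lay higher at 72 h, where the median over all genes was 0.03. Control replicate 3 of this time had the highest value (0.57) on the largest component of the variance within groups. Gene loadings on that component fell with the mean log2 level (Spearman rho = -0.618 across genes), so highly expressed genes read lower in that array. Of the mitochondrial ribosome 70 of 71 genes were positive, with a median of 0.16 (MRPS31 at 0.37, SE 0.12, and MRPS5 at 0.22, SE 0.08). The medians were 0.16 for respiratory complex I (33 of 34, NDUFV2 at 0.33), 0.17 for complexes II to IV (23 of 23, COX6C at 0.36), 0.15 for ATP synthase (14 of 15, ATP5F1A at 0.18) and 0.15 for mitochondrial dynamics and mitophagy (31 of 34, TOMM20 at 0.33). They were 0.15 for the proteasome (28 of 28, PSMD8 at 0.25), 0.17 for mitosis (31 of 31, CCNB2 at 0.25), 0.14 for DNA replication (38 of 39, CDC45 at 0.21), 0.08 for histones (24 of 26) and 0.13 for cytosolic ribosomal proteins (48 of 49, RPS24 at 0.26). ER chaperones had a median of 0.09 (24 of 29, SEL1L at 0.32), cholesterol synthesis genes 0.14 (17 of 19, INSIG1 at 0.27), autophagy and lysosome genes 0.12 (27 of 32, ULK2 at 0.31) and neurodegenerative disease genes 0.10 (26 of 30, BACE1 at 0.22 and ATXN2 at 0.27). NF-kB and cytokine genes (-0.13, 2 of 20 positive, ICAM1 at -0.29) and neuronal genes (-0.09, 7 of 25, STX1A at -0.24 and NTRK2 at -0.28) lay lower. Camera called these 16 lists; no member passed over all genes, and adjusted over the list alone 1 rose among ER chaperones and 1 in mitochondrial dynamics. With an estimated correlation none was called (adjusted p = 0.776 to 0.778), and control replicate 3 of this time, with the lowest median correlation of all arrays (0.926), moved with them: without it 4 lists were called, and the medians were 0.06 for the mitochondrial ribosome, 0.06 for complex I, 0.03 for mitosis and 0.01 for neurodegenerative disease genes.

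At 96 h TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein, rose by 0.52 (SE 0.10, adjusted p = 0.0407), from 7.18 ± 0.24 in control (SD, n = 3) to 7.72 ± 0.14, 7.60 ± 0.16 and 7.78 ± 0.15 (SD, n = 3 each). MIR199A1, a microRNA precursor gene, was lower than control by 0.90 (SE 0.16, adjusted p = 0.0250), at 4.70 ± 0.34 in control and at 3.57 ± 0.14, 4.02 ± 0.27 and 3.83 ± 0.35 with the siRNAs (SD, n = 3 each). The mean level of MIR199A1 over all arrays, 3.94, lies below the limit of the filter on dim probes (6.29), which removes it. The siRNA groups lay nearer to this mean than the 96 h controls, so the difference cannot be placed in the siRNA groups rather than in the controls. No other gene passed in limma, and 1799 had an unadjusted p under 0.05. Without the 7 low-correlation arrays, 2 of them among the 3 controls of this time, neither passed (TSC22D3 at 0.28 and MIR199A1 at -0.51). The number of genes called also rested on single control arrays: 445 without replicate 2, which lies above the correlation fence, and 0 without replicate 3.

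Cytosolic ribosomal protein genes lay higher at 96 h (median 0.19, 47 of 49 positive, RPL30 and RPS28 at 0.52 each), as did complexes II to IV (0.28, 23 of 23, COX6C at 0.57 and COX7C at 0.63), complex I (0.22, 31 of 34, NDUFB8 at 0.54 and NDUFA12 at 0.65), hypoxia and glycolysis genes (0.15, 27 of 31, EGLN3 at 0.43), the mitochondrial ribosome (0.12, 59 of 71, MRPL2 at 0.48), the proteasome (0.24, 23 of 28, PSMA5 at 0.44), ATP synthase (0.15, 13 of 15) and mitosis genes (0.15, 25 of 31, AURKA at 0.26). Small RNA machinery genes lay lower (-0.12, 4 of 16 positive), with AGO2, the slicing Argonaute, at -0.47 (SE 0.16). Camera called these 9 lists, and over all genes no member passed. Adjusted over the list alone, 9 ribosomal protein genes, 5 of complex I, 3 of complexes II to IV, 3 of glycolysis and 4 of the mitochondrial ribosome rose. With an estimated correlation none was called (adjusted p = 0.776 to 0.778), and without the 7 low-correlation arrays the medians turned to -0.06 for complex I, -0.05 for complexes II to IV and -0.02 for cytosolic ribosomal proteins. Without control replicate 3 alone they were 0.05, 0.02 and 0.02, and none of these 3 lists was called.

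Lists that passed at no time were interferon-stimulated genes (lowest adjusted p 0.138), p53 targets (0.0775), apoptosis genes (0.147), fatty acid synthesis genes (0.0570) and NRF2 targets (0.0629). Markers of blood cells, fibroblasts, HeLa-like epithelium and neural character were not called either (lowest adjusted p 0.275). Their mean log2 level over all arrays was 5.19, 5.59, 6.12 and 9.14.

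Each siRNA was also compared with control on its own. With siRNA2 PTDSS1 fell at 72 h (-0.55, adjusted p = 0.0380) and at 96 h (-0.73, adjusted p = 0.00557), from 10.35 ± 0.14 in control to 9.61 ± 0.18 (SD, n = 3 each). MIR199A1 was lower with siRNA1 than in control at 96 h (-1.14, adjusted p = 0.0132), and HSF2BP, the gene of a heat shock factor 2 binding protein, rose with siRNA3 at 96 h (0.51, adjusted p = 0.0436). RNU5D-1 fell with siRNA1 at 24 h (-3.24, adjusted p = 8.4e-05), where its level was 12.23 ± 0.01 in control and 8.99 ± 2.35 with siRNA (SD, n = 2 each). Without siRNA1 replicate 3 this difference was -1.58 and no longer passed, and without replicate 4 it was -4.91. U5 genes are near-identical copies, so this level is uncertain. With the 7 low-correlation arrays left out, 1 control array remained at 24 h and 1 at 96 h, and other groups supplied the spread. MIR199A1 (-0.77), HSF2BP (0.49) and RNU5D-1 (-3.24) no longer passed there. PTDSS1 passed at 72 h (-0.65, adjusted p = 5.44e-07) and was at -0.79 at 96 h, against that 1 control array. PTDSS1, MIR199A1, HSF2BP and RNU5D-1 were the genes that passed in the 12 limma comparisons over all arrays. The comparisons without a gene past 0.05 had between 38 (siRNA2 at 48 h) and 3717 (siRNA3 at 48 h) genes with an unadjusted p under 0.05. Of the 4 siRNA3 arrays at 48 h 2 have low correlations, and without the 7 arrays that count was 282. Also without them 28, 6 and 16 genes passed for siRNA1, siRNA2 and siRNA3 at 72 h, and 1 each for siRNA1 and siRNA2 at 48 h. In fits without 1 array PTDSS1 passed in 1 of 9 at 72 h (-0.65 to -0.50) and in 2 of 6 at 96 h (-0.84 to -0.67), HSF2BP in 2 of 6 (0.44 to 0.58) and MIR199A1 in 1 of 6 (-1.32 to -0.98).

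No gene passed with all 3 siRNAs in the same direction at any time over all arrays, and TFPI2, a protease inhibitor gene, did at 72 h without the 7 low-correlation arrays, chosen after its values were seen. At an unadjusted p under 0.05 in each siRNA, limma gave 7, 1, 295 and 191 such genes at 24, 48, 72 and 96 h, and 5, 7, 68 and 147 without these arrays. The 3 siRNAs of a time share its controls, so the number of such genes expected by chance is not known here. Across genes, which are not independent replicates, the 72 h differences of the siRNAs from control correlated at 0.818, 0.833 and 0.850, where unchanged groups simulated with shared controls gave mean correlations of 0.393 to 0.442 and single draws from -0.513 to 0.942. The covariance was 0.0284, 0.0310 and 0.0346, against simulated means of 0.00760 to 0.00927 and highest draws of 0.0510, 0.0655 and 0.0513. With the controls split between the compared siRNAs, the correlations were 0.0931, 0.146 and 0.221. Without the 7 low-correlation arrays they were 0.424, 0.438 and 0.496 with shared controls, against simulated means of 0.477 to 0.510, and -0.0997, -0.0676 and -0.0207 with split controls. These simulated means used deviations from group means that still included the 7 arrays, so they are not an exact reference.

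The siRNAs differed from one another in 1 gene at 24 h, 3 genes at 72 h and 1 gene at 96 h, by limma's F-test over the 3 siRNA groups. PTDSS1 differed at 72 h (adjusted p = 3.374e-04) and 96 h (adjusted p = 8.437e-05), with 9.87 ± 0.09 at 72 h for siRNA2 (SD, n = 4) against 10.47 ± 0.11 and 10.56 ± 0.08 for siRNA1 and siRNA3 (SD, n = 5 each). UHMK1, a kinase gene, differed at 72 h (adjusted p = 0.00113), with 9.80 ± 0.04, 10.11 ± 0.06 and 10.43 ± 0.05 for siRNA1, siRNA2 and siRNA3 (SD, n = 5, 4 and 5). CS, the citrate synthase gene of the mitochondrial matrix, was lower with siRNA1 at 72 h (10.10 ± 0.12) than with siRNA2 (10.49 ± 0.07) or siRNA3 (10.59 ± 0.14), with an adjusted p of 0.0139. At 24 h the gene was RNU5D-1 (adjusted p = 0.00906), and at 48 h no gene passed while 2022 had an unadjusted p under 0.05 (1 passed and 237 had an unadjusted p under 0.05 without the 7 low-correlation arrays). PTDSS1 and UHMK1 passed at 72 h in all 14 fits that left out 1 siRNA array, CS in 10 of 14. On the arrays of the compared time only, with fewer degrees of freedom, no gene passed at 72 or 96 h. When the 7 low-correlation arrays were left out, 119 genes passed at 72 h and 40 at 96 h.

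**Figure D3:**
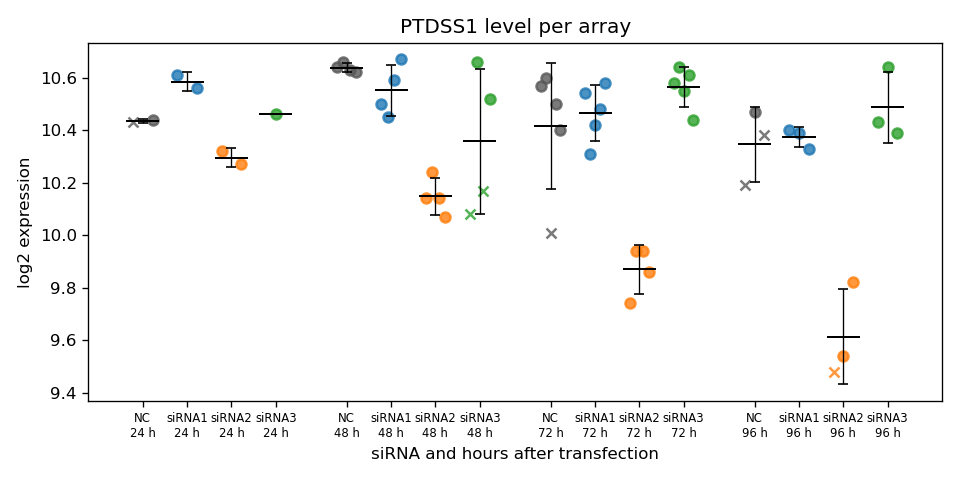
The log2 level of PTDSS1 on each array (y axis) is plotted by siRNA and hours after transfection (x axis), with black lines for group means, bars for SD and crosses for the 7 low-correlation arrays. With siRNA2 the mean is 10.29 at 24 h, 10.15 at 48 h, 9.87 at 72 h and 9.61 at 96 h.

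The effect of the siRNAs was compared between times. By limma's F-test over the 4 times no gene differed (739 with an unadjusted p under 0.05), MIR199A1 having the smallest adjusted p at 0.485, and none differed between 72 h and 48 h (3250 with an unadjusted p under 0.05). In control cells no gene passed from 24 to 48 h (1994 with an unadjusted p under 0.05), where SNORD50B, a small nucleolar RNA gene, was at 1.16 (SE 0.26) and DHRS2, a dehydrogenase gene, at -0.62 (SE 0.14), with an adjusted p of 0.443 each. None passed from 72 to 96 h either (1260 with an unadjusted p under 0.05), where the pseudogene SPDYE7P was at 1.08 (SE 0.21, adjusted p = 0.143) and MIR199A1 at 0.85 (SE 0.18, adjusted p = 0.172). Between 72 and 96 h in control cells complex I (-0.20), complexes II to IV (-0.20), the proteasome (-0.19), histones (-0.11), both groups of ribosomal proteins (-0.07 each) and stress response targets (-0.06) lay lower, and small RNA machinery genes (0.14) lay higher by camera. From 24 to 48 h mitosis (0.24) and heat shock genes (0.15) lay higher and histones (-0.17) and NF-kB genes (-0.17) lower. Over all genes no member of these lists passed, and adjusted over the list alone 2 heat shock genes rose. Of these control arrays 24 h replicate 2, 72 h replicate 3 and 96 h replicates 1 and 3 have low correlations. Without the 7 arrays the medians from 72 to 96 h were 0.01 for complex I, 0.07 for complexes II to IV and -0.06 for the proteasome, cytosolic ribosomal proteins turned to 0.07, and of the 4 lists named from 24 to 48 h histones alone (-0.15) were still called. With an estimated correlation over all arrays none of these lists was called (adjusted p = 0.942).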

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

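The splits of the arrays with all 54 arrays or without the 7 low-correlation arrays, the count of gene lists held without these arrays and the test of the 5 genes were chosen after the results were seen, and the split of the 72 h lists without the 7 arrays, the cross-time test and the test of WFS1 silencing order were written before theirs, though PTDSS1, UHMK1 and CS had been seen at the other times.

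Single arrays stood far from the other arrays of their group, by a gap beyond Dixon's 95% critical value, in 6 of the 80 groups and measures tested, where chance gives about 1 in 20. Control replicate 3 at 72 h was such an array for 3 of them: its median correlation was 0.926 (0.992 to 0.993 in the others), ISOC1 was at 8.64 (9.07 to 9.23) and UHMK1 at 9.59 (10.11 to 10.31). The others were MIR199A1 in control replicate 3 at 48 h (3.61, others 3.87 to 3.91), CS in siRNA3 replicate 4 at 72 h (10.34, others 10.64 to 10.68) and the median correlation of siRNA1 replicate 3 at 72 h (0.991, others 0.993). Groups of 3 or fewer arrays were not tested.

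The siRNAs differed from one another by limma's F-test in RNU5D-1 at 24 h (adjusted p = 0.00906), in PTDSS1 (3.374e-04), UHMK1 (0.00113) and CS (0.0139) at 72 h and in PTDSS1 at 96 h (8.437e-05). CS passed in 10 of the 14 fits that left out 1 siRNA array, with adjusted p up to 0.219, and RNU5D-1 in 2 of 4. Outside the named genes, 13163 probe sets had no symbol or several. Of these 2 passed for the mean siRNA effect at 96 h (1446 with an unadjusted p under 0.05) and none at the other times by limma (456, 173 and 1920 with an unadjusted p under 0.05 at 24, 48 and 72 h), and none without the 7 low-correlation arrays (182, 259, 695 and 604).

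Other splits of the same arrays into groups of the same sizes were counted with the real one included, without correction for the number of such counts. Among so many counts, a share of 1 to 3 in 100 does not by itself exclude chance. For the mean siRNA effect at 72 h 3 of 100 splits were as large. The real split gave 2 genes, another gave 5, and without control replicate 1 the real split gave 0. At 96 h chance cannot be excluded (19 of 100, 2 against 4866). For differences among siRNAs the real split gave the most genes at 72 h, by a narrow margin (1 of 100, 3 against 2), and chance cannot be excluded at 96 h (15 of 100, 1 against 19). It cannot be for siRNA2 at 72 h (6 of 100, 1 against 1) or for lists at 48 h (18 of 100, 16 against 20) and 96 h (64 of 100, 9 against 19). For single siRNAs at 96 h the 10 splits are too few for a share under 0.05 (4, 6 and 2 as large, 1 gene each against 3, 2714 and 1).

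Where the real count was 0, every split is as large by construction, so these counts test nothing. This holds at 48 h for the mean siRNA effect (100 of 100, highest other 5487, and 0 without the 7 arrays), for differences among siRNAs (100 of 100, highest other 0) and for single siRNAs (35 of 35 each, highest other 0, 0 and 4463). It also holds for siRNA1 and siRNA3 at 72 h (highest other 0 and 8), for genes changed alike by all 3 siRNAs at 48, 72 and 96 h (highest other 0, 0 and 20), for control cells at 96 h against 72 h (56 of 56, highest other 10722) and for 72 h against 48 h (highest other 4735). Splits that called 2714 to 10722 genes point to a structure of the samples.

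At 72 h 16 gene lists were called, most with higher mitochondrial, proteasome and cell division genes, and 0 with an estimated correlation. Of these 4 were called in the same direction without the low-correlation arrays, so these arrays, 1 of them a 72 h control, are a candidate source of most of the calls. In 29 of 100 splits as many lists were called (16 against 20), so chance cannot be excluded, nor can it be for the 4 lists called without the 7 arrays (68 of 100, 4 against 14). A small rise of mitochondrial ribosome genes after silencing, with a median of 0.06 without the 7 arrays, stays open as a biological explanation.

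Without the 7 arrays 119 genes differed among siRNAs at 72 h, more than in any other split counted (1 of 100 splits, 119 against 41). This makes chance less likely, though it is 1 of many uncorrected counts. Technical differences among the 72 h arrays alone are argued against by the other times: the siRNA that deviated most at 72 h deviated the same way in 95.8% of the genes at 48 h and in 100% at 96 h, where shuffled labels reached at most 95.0% and 92.4%, a small margin at 48 h. At 96 h alone chance cannot be excluded (24 of 100 splits, 40 against 3609). Whether the degree of WFS1 silencing orders these genes cannot be told apart, since the siRNA with the middle WFS1 level was the middle one in 46.2% of the genes (33.3% by chance) while WFS1 itself did not pass among siRNAs (limma F-test, unadjusted p = 0.145). Action of each siRNA on other transcripts remains an untested hypothesis, as does handling tied to each siRNA at every time, and siRNA sequences were not analysed here.

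Without the 7 arrays 6 genes passed for the mean siRNA effect at 72 h, WFS1 among them, and none when the replicate block was added. Another split also gave 6, so 2 of 100 splits were as large, and among many uncorrected counts this share does not exclude chance. A chance deviation of the 72 h controls is argued against for the other 5 genes as a set, which moved the same way at 48 and 96 h by a mean log2 of 0.155, where shuffled labels reached at most 0.127. This holds for the set without the 7 arrays, where TFPI2 at 48 h was an exception (0.03) and the 96 h values rest on 1 control array. Over all arrays at 96 h TFPI2 was at 0.04 and MBTPS1 at 0.0011, so neither showed its 72 h direction beyond the spread there. An effect of WFS1 silencing on these genes is a hypothesis found and tested on the same arrays.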

How the results depend on the processing

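Leaving out the 7 low-correlation arrays, alone or with the replicate block, and the array SD as a covariate were chosen after seeing the data. WFS1 kept its direction in every comparison and alternative run. Counts moved both ways without the 7 arrays of low signal spread, and the cause of the changes below was not tested unless named. Counts are genes changed, in limma, unless lists or differences among siRNAs are named. A list is given as reversed where camera's test changed direction, which can happen while the median keeps its sign, as for ER chaperones at 96 h after quantile normalization, neurodegenerative disease genes at 72 h without the low-correlation arrays and stress response at 72 h with the array SD as a covariate. Each of the 48 main results and 89 values of named genes and lists was paired with each alternative run for it. Of these pairs, 345 and 579 stayed on their side of the threshold or near their count under the alternatives, and 428 and 683 when 1 array was left out. For the main results, counts moved in 104 pairs, a call was lost in 7 and gained in 3 under the alternatives. When 1 array was left out these were 69, 17 and 1 pairs. Named genes and lists lost their call in 95 and gained one in 47 cases under the alternatives, and in 80 and 19 when 1 array was left out.

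On the arrays of the compared time only, which leaves fewer degrees of freedom, counts were 0 for siRNA1 and for differences among siRNAs at 24 h, 0 for the mean effect, siRNA2 and differences at 72 h (WFS1 at -0.39, no longer past the threshold), and 0 for the mean effect, siRNA1, siRNA2, siRNA3 and differences at 96 h. Control cells at 48 h against 24 h gave 90 on the arrays of the compared times only.

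With the replicate block, siRNA1 and differences at 24 h gave 0, the mean effect at 72 h 0 (WFS1 at -0.39, not past the threshold), siRNA2 at 72 h 0, the mean effect at 96 h 1, siRNA3 at 96 h 0, control cells at 96 h against 72 h 2 and lists at 24 h 6, with complex I at 24 h at 0.01 and its test reversed. With the replicate block and the low-correlation arrays left out, siRNA1 at 24 h gave 0, siRNA1 and siRNA2 at 48 h 1 and 1, the mean effect at 72 h 0 (WFS1 at -0.40, not past the threshold), the 3 siRNAs at 72 h 5, 2 and 1, differences at 72 h 36, the mean effect at 96 h 1, the 3 siRNAs at 96 h 2, 3 and 0 and differences at 96 h 4. Same-numbered arrays did not deviate together: their correlations ran from -0.529 to 0.405 at 48 h (5 of 24 pairs over 0.1), from -0.408 to 0.368 at 72 h (10 of 27) and from -0.632 to 0.528 at 96 h (6 of 18). In 9 of 47 arrays the best match had the same number. This gives no sign that the numbers pair the arrays, but with the low-correlation arrays included it cannot rule a pairing out.

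With the filter on dim probes the mean effect at 96 h gave 1, siRNA1 at 96 h 0, lists at 24, 48 and 72 h 5, 3 and 9, and the stress response list at 72 h was at 0.10 with its test reversed. With quantile normalization again, siRNA1 at 24 h gave 7, siRNA2 at 48 h 2, differences at 48 h 4, the mean effect at 72 h 1 (WFS1 at -0.34, not past the threshold), the 3 siRNAs at 72 h 25, 4 and 9 (WFS1 with siRNA3 at -0.40, now past it), differences at 72 h 32, the mean effect at 96 h 28, the 3 siRNAs at 96 h 4, 13 and 18, differences at 96 h 4, control cells at 96 h against 72 h 53 and lists at 24, 48 and 72 h 2, 1 and 2. Reversed were the stress response list at 24 h (-0.0328) and 72 h (-0.0232), complex I at 24 h (-0.00494) and 48 h (0.00968), neurodegenerative disease genes at 72 h (-0.00546) and ER chaperones at 96 h (0.0112).

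With the label number as a covariate, differences at 24 h gave 0, the mean effect at 96 h 0, siRNA1 at 96 h 0, siRNA3 at 96 h 5, lists at 96 h 17, and neurodegenerative disease genes at 96 h reversed to 0.0204. With an intensity trend and robust variance the mean effect at 72 h gave 1 (WFS1 at -0.39, not past the threshold). An estimated correlation gave 0, 0, 0 and 0 lists at 24, 48, 72 and 96 h. For the mean over 2 siRNAs, leaving out siRNA1 gave 0 at 96 h and neurodegenerative disease genes at 96 h at -0.00917. Leaving out siRNA2 gave 0 at 72 h (WFS1 at -0.38, not past the threshold) and neurodegenerative disease genes at 96 h at 0.0058. Leaving out siRNA3 gave 0 at 72 h (WFS1 at -0.36, not past the threshold), 0 at 96 h, 4 lists at 48 h and the stress response list at 72 h at 0.0506 with its test reversed.

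Without the low-correlation arrays, siRNA1 and differences at 24 h gave 0, siRNA1 and siRNA2 at 48 h 1 and 1, differences at 48 h 1, the mean effect at 72 h 6, the 3 siRNAs at 72 h 28, 6 and 16 (WFS1 with siRNA3 at -0.46, now past the threshold), genes changed alike by all 3 siRNAs at 72 h 1, differences at 72 h 119, the mean effect at 96 h 1, siRNA2 and siRNA3 at 96 h 2 and 0, differences at 96 h 40, and lists at 48, 72 and 96 h 0, 4 and 4. Reversed were the proteasome (-0.0442), stress response (-0.02) and complex I (-0.15) at 24 h, stress response (-0.0134) and neurodegenerative disease genes (0.0059) at 72 h, and cytosolic ribosomal proteins (-0.0211), complexes II to IV (-0.05), complex I (-0.0575), ER chaperones (-0.0339) and stress response (-0.0033) at 96 h.

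With the array SD as a covariate, siRNA1 at 24 h gave 4, siRNA2 at 48 h 1, differences at 48 h 2, the mean effect at 72 h 19, the 3 siRNAs at 72 h 28, 6 and 37 (WFS1 with siRNA3 at -0.42, now past the threshold), genes changed alike by all 3 at 72 h 1, differences at 72 h 73, the mean effect at 96 h 4, siRNA2 and siRNA3 at 96 h 3 and 5, differences at 96 h 16, control cells at 96 h against 72 h 453 and lists at 24, 48 and 72 h 3, 5 and 10. Reversed were ER chaperones (-0.0086), stress response (-0.0268), complex I (-0.0268) and neurodegenerative disease genes (-0.0204) at 24 h, complex I at 48 h (0.0358), stress response at 72 h (2.5e-04) and ER chaperones at 96 h (-0.0012).

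Leaving out 1 array in turn at 24 h gave 0 to 1 for the mean effect (1 without siRNA1 replicate 4), 0 to 8 for siRNA1 (without replicates 3 and 4), 0 to 4 for differences among siRNAs, -0.0442 to 0.41 for the proteasome, 0.05 to 0.34 for mitosis (no longer called at 0.05), -0.0083 to 0.12 for ER chaperones, -0.02 to 0.10 for stress response and -0.15 to 0.37 for complex I, the lists without control replicates 2 and 4. Control cells at 48 h against 24 h gave 0 to 6 and differences among times 0 to 1, both highest without control replicate 4 of 24 h. At 48 h siRNA3 gave 0 to 4948 and differences among siRNAs 0 to 28, both highest without siRNA3 replicate 2, and lists 10 to 19 without siRNA3 replicates 3 and 4. At 72 h the mean effect gave 0 to 4 (without control replicates 1 and 2), WFS1 -0.43 to -0.37, siRNA2 0 to 1, siRNA3 0 to 1, WFS1 with siRNA3 -0.52 to -0.38, lists 4 (without control replicate 3) to 20 (without control replicate 1), stress response -0.0134 to 0.12 and neurodegenerative disease genes 0.0059 to 0.14, both lowest without control replicate 3. At 96 h the mean effect gave 0 (without control replicate 3) to 445 (without control replicate 2), siRNA1 0 to 4, siRNA2 0 to 81 (81 without control replicate 1), siRNA3 0 to 771 (771 without control replicate 2), differences 1 to 2, lists 5 to 13, ER chaperones -0.0289 to 0.12, stress response 0.0086 to 0.0811 and neurodegenerative disease genes -0.0911 to 0.0514. Control cells at 96 h against 72 h gave 0 to 45 (45 without control replicate 2 of 96 h). Without the single siRNA3 array of 24 h the mean effect and siRNA3 at 24 h have no value, and the mean of probe sets tests nothing for WFS1, which has 1 probe set. Array weights did not converge and were not used.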

Other observations

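Leaving out the low-correlation arrays, using the array SD as a covariate, averaging over times and comparing siRNA deviations between times were chosen after seeing the data, and so were the genes named here.

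Without the 7 low-correlation arrays, 4 genes rose and 2 fell with WFS1 siRNA at 72 h, while none passed when the replicate block was added. MBTPS1, whose product is the protease that cleaves ATF6 and SREBP, rose by 0.31 (SE 0.05, adjusted p = 0.00875), PTPMT1, a mitochondrial phosphatase gene of cardiolipin synthesis, by 0.27 (SE 0.05, adjusted p = 0.0146), ISOC1 by 0.26 (SE 0.04, adjusted p = 0.00397) and PDIA4 by 0.25 (SE 0.05, adjusted p = 0.0405). TFPI2, a protease inhibitor gene, fell by 0.50 (SE 0.08, adjusted p = 0.00397) and passed with each of the 3 siRNAs. WFS1 fell by 0.40 (SE 0.07, adjusted p = 0.0171). The list of ER chaperones, PDIA4 among them, was not called in these arrays (median 0.00333, camera adjusted p = 0.724). At 48 h the differences were 0.18 for MBTPS1, 0.23 for PTPMT1, 0.10 for ISOC1, 0.08 for PDIA4 and 0.03 for TFPI2, and none passed in limma (171 genes with an unadjusted p under 0.05). At 96 h DNASE1L3 alone passed (1.33, SE 0.23, adjusted p = 0.0291), against a single control array assumed to vary like the other groups. Over all arrays its difference at 96 h was 0.39 (SE 0.20, adjusted p = 0.523). Among the 28, 6 and 16 calls of siRNA1, siRNA2 and siRNA3 at 72 h, TFPI2 was shared by all 3 pairs and ISOC1 by siRNA2 and siRNA3. Independent lists would share 0.00565, 0.00565 and 8.69e-04 lower genes and 0.00130 higher genes for siRNA2 and siRNA3. The 3 comparisons use the same control arrays, so their calls are not independent. These expected values are therefore no valid reference, and the overlap cannot be set against chance here. In 100 draws of unchanged groups with shared controls, no gene was called by more than 1 siRNA by limma, while 1 of 50 further draws with another seed gave 1 such gene. The same 100 draws gave a mean of 200 calls over the 3 siRNAs and up to 10440. All these draws used deviations from group means that still included the 7 arrays. Their spread is therefore not that of the fit without these arrays, and they give no valid rate for its calls.

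Without the 7 arrays 119 genes differed among siRNAs at 72 h, and fewer when the replicate block was added. These 119 genes were mostly lower with siRNA1. For 64 of them siRNA1 deviated most from the mean of the 3 siRNAs (63 lower), for 21 siRNA2 (13 lower) and for 34 siRNA3 (22 higher). ELOVL1, a fatty acid elongase gene, differed from control with siRNA1 by -0.44, -0.56 and -0.77 at 48, 72 and 96 h, and PTDSS1 with siRNA2 by -0.49, -0.65 and -0.79. Both passed in limma at 48 and 72 h, while the 96 h values rest on 1 control array. Over all arrays ELOVL1 was at -0.44, -0.39 and -0.17 and did not pass (adjusted p = 1, 0.513 and 0.927, and 0.287 in the F-test among siRNAs at 72 h). UHMK1 deviated from the mean of the siRNAs about as far down with siRNA1 (-0.18, -0.31 and -0.27) as up with siRNA3 (0.18, 0.32 and 0.32). Its difference from control was larger with siRNA1 (-0.26, -0.42 and -0.39) than with siRNA3 (0.10, 0.21 and 0.19), where it did not pass at 48 or 72 h. Of the 119 genes 21 were also among the 40 that differed at 96 h, and 4 belonged to any of the gene lists, where 4.93 were expected (exact hypergeometric test over genes, not samples, p = 0.731).

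Averaged over the 4 times, WFS1 fell by 0.30 (SE 0.05, adjusted p = 0.00234), and TOMM20, a mitochondrial import receptor gene (0.35, SE 0.06, adjusted p = 0.00337), CALU, an ER calcium-binding protein gene (0.38, SE 0.08), CCNC (0.31, SE 0.06), TSC22D3 (0.27, SE 0.05) and RFK (0.20, SE 0.04) rose. Without the 7 arrays none passed in limma (526 with an unadjusted p under 0.05), and WFS1 was at -0.29 (adjusted p = 0.0751). With the array SD as a covariate 36 genes passed (29 higher, 7 lower, smallest adjusted p = 9.2e-06), so this count depends on how the 7 arrays are treated.

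A single component held 52.7% of the variance left within groups and the next 8.78%. Array values on the first component correlated with the median correlation at -0.744, and they were positive in the 7 low-correlation arrays. Gene loadings on it correlated with the mean log2 level at -0.618 (Spearman, across genes), so highly expressed genes read lower in these arrays. Lists of highly expressed genes can therefore move with these arrays, which was not tested list by list.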
